A study of Mus musculus with 4 samples.

How the data were processed

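RNA sequencing of bone marrow-derived macrophages from C57BL/6 mice was available for 4 libraries, 2 transfected with a control siRNA and 2 with siRNAs against IRF2. Per the labels, cells were cultured for 5 days with M-CSF at 50 ng/ml and 10% fetal bovine serum, transfected with 50 nM siRNA and collected 48 h after transfection. Libraries were grouped by the siRNA in their label. The replicate numbers 1 and 2 were not taken to pair a control library with an IRF2 siRNA library, since the labels name no pairing.

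The deposited table holds raw counts of reads per gene, 1 column per library. Per the labels, reads were demultiplexed with bcl2fastq 2.18.0.12, aligned to mm10 with STAR 2.5.2b and counted with HTSeq 0.6.0. DESeq2 is named there without a version, and no output of it is in the table. The annotation release and the strand setting of the counting are not given in the sources used here. Values were checked to be whole numbers with a different total in each library. The table has 48795 genes and 5 summary rows that name no gene, which were left out of all gene tests. Counts summed over genes were 29862296 and 32273565 for control replicates 1 and 2, and 26378584 and 26895100 for IRF2 siRNA replicates 1 and 2. Column totals including the summary rows were 39505407, 42556786, 34420773 and 34952567 in the same order. Of these, 5.07%, 6.85%, 5.58% and 6.1% lay in no gene, 4.38%, 4.17%, 4.71% and 4.49% were ambiguous between genes, and 15.0%, 13.1%, 13.1% and 12.5% aligned to more than 1 place. The other 2 summary rows, for low alignment quality and unaligned reads, were 0 in every library. The 10 most abundant genes took 11.5%, 9.64%, 10.6% and 9.99% of gene counts. Gene symbols, coordinates, transcript lengths, GC content and overlaps of exons were taken from GENCODE M21 on GRCm38, the assembly of mm10. Symbols were found for 48349 genes, and 37 genes tested had none.

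Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at its minimum count of 10 and minimum total of 15, which left 13495. Libraries were scaled by TMM, with factors of 0.9729, 1.009, 1.005 and 1.014. Dispersions were estimated with estimateDisp, and a model with the siRNA group was fitted with glmQLFit, with legacy = FALSE, and tested with glmQLFTest. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 12.6%. Expression is given in TMM-normalised CPM as the mean ± SD over the 2 libraries of a group. The statistic of a chi-square comparison of replicates was 51.1 per degree of freedom for the control libraries and 9.94 for the IRF2 siRNA libraries, so in neither group were replicates copies or re-samplings of 1 library.

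Gene lists were tested with camera in limma 3.58.1, with its preset correlation of 0.01 between genes, for lists with at least 3 tested members. The adjustment was made within the 24 biological lists and within the 10 of 13 technical lists that had enough members. The biological lists cover glycolysis and other metabolism, interferon responses, antigen presentation, innate sensing, activation, identity, the cell cycle, stress responses and RNA interference, and the technical lists cover mitochondrial, histone and ribosomal protein mRNAs and markers of other cell types. Members past the threshold are given both over all genes and adjusted over the list alone. A further list of 20 progenitor markers was used for 1 test of the closing section.

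The lists, tests, thresholds and most alternatives were set before the data were examined. So was the rule for naming genes. It takes Irf2, then the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and both IRF2 siRNA libraries on 1 side of both control libraries. Symbols made of Gm and a number, or ending in Rik, are passed over. From each list it takes up to 4 called members with the smallest p, or the 2 with the smallest p where none is called. The rule named 97 genes, of which 2, and the counts of called members of their list, are not reported here. Other genes are marked in the text as chosen after their values were seen.

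Alternatives covered scaling (DESeq2 size factors, library size alone), filtering (no filter, a CPM of 1 or more in at least 2 libraries), testing (DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, legacy = TRUE), the replicate number as a block, a threshold of 0.01, a minimum absolute log2 fold change of 1, and leaving out each library in turn. A group left with 1 library is then assumed to vary like the other group. Far more genes pass over all genes without a control library, so higher counts of list members in those fits are not by themselves a response of the list. For lists they also covered camera with an estimated correlation, camera on ranks, and fry. With an estimated correlation, camera draws its degrees of freedom from the libraries, and 4 libraries in 2 groups leave few. With the preset it draws them from the number of genes. The estimated form can therefore hardly call a list here, so its adjusted p-values count little against one. A correction for transcript length and GC content, a loess trend per library removed as an offset, was added after the data were seen and covered 13458 genes.

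The procedure was tested on simulated counts with the dispersions of these libraries and 200 changed genes, where 13281 genes in all passed the filter. Of 50 genes changed at each fold, it called 8 at 1.5-fold, 40 at 2-fold, 39 at 3-fold and 49 at 4-fold, with 6 false calls among 142. With no gene changed it called 0 genes and 0 lists. The simulated genes were drawn independently of each other, at the trended dispersion. The run with no change therefore cannot show how often lists are called falsely where their genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.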

Results

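RNA sequencing measured gene expression in bone marrow-derived macrophages of C57BL/6 mice. These are primary cells grown from marrow over 5 days with 50 ng/ml of M-CSF, the growth factor that directs macrophage differentiation, and 10% fetal bovine serum. The cells were transfected with 50 nM of a control siRNA or of siRNAs against IRF2, and RNA was taken 48 h later. An siRNA is a short RNA duplex that directs the degradation of a matching mRNA, and IRF2 is a transcription factor that binds interferon-responsive promoter elements and is known mainly as a repressor there. The series holds 4 libraries, 2 per group. Reads counted in genes numbered 29862296 and 32273565 in control replicates 1 and 2, and 26378584 and 26895100 in IRF2 siRNA replicates 1 and 2. Between 18997 and 20150 genes had at least 1 read per library. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

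The comparison asked which transcripts differ when Irf2 expression is reduced. Irf2 itself, on chromosome 8 at positions 46739732 to 46847458 of mm10 on the plus strand, had 4758 and 4934 reads in the control libraries and 1482 and 1529 reads in the IRF2 siRNA libraries. Its level was 157.8 ± 8.66 CPM (SD, n = 2) with control siRNA and 56.0 ± 0.108 CPM (SD, n = 2) with IRF2 siRNA, which is 2.81-fold lower. The log2 fold change was −1.49 with a standard error of 0.11, and the edgeR quasi-likelihood test gave an adjusted p = 0.00477. Both libraries labelled IRF2 siRNA therefore held less Irf2 mRNA than both controls. No other member of the list of interferon regulatory factors passed the test among 10 tested. Irf2bpl and Irf4 had log2 fold changes of 0.49 and 0.47, with edgeR adjusted p-values of 0.119 and 0.171, and these 2 were the members past the threshold when adjusted over the list alone. The list's median was −0.0071, above 0 when scaled by library size alone, with a limma camera adjusted p = 0.628. Leaving out control replicate 1 gave 2 members that rose, and leaving out replicate 2 gave 2 that rose and 2 that fell.

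**Figure D1:**
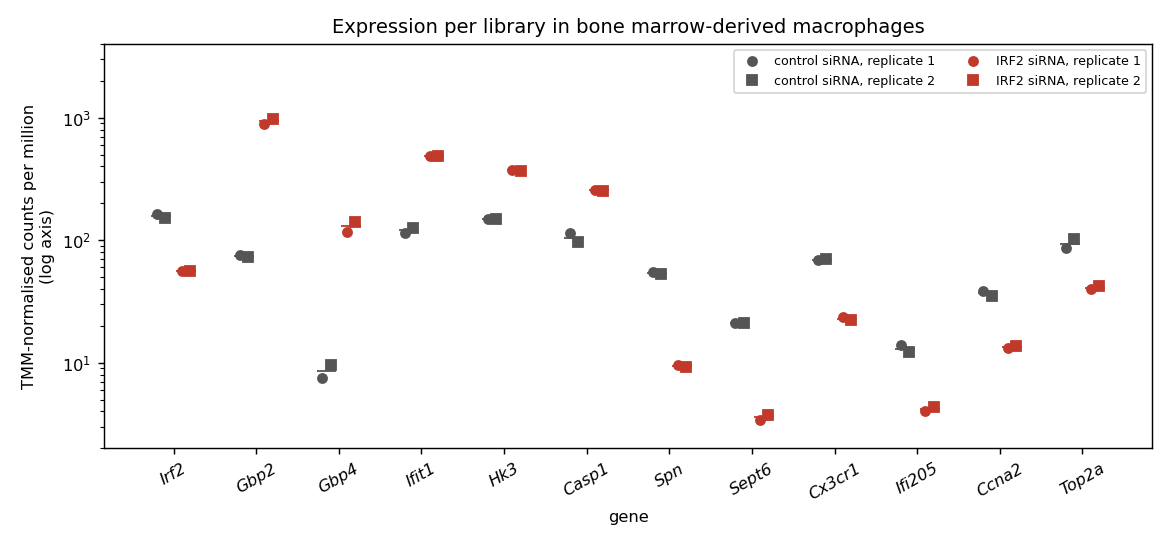
TMM-normalised expression of 12 genes in each of the 4 libraries, in CPM on a log axis. Grey symbols are control siRNA, red symbols are IRF2 siRNA, circles and squares are replicates 1 and 2, and short lines are group means. For each gene shown, both IRF2 siRNA libraries lie on 1 side of both control libraries.

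With IRF2 siRNA, 8 of 10 genes tested for guanylate-binding proteins, a family counted after the values were seen, rose, while 17 of 34 cell cycle genes fell. Type I interferon-stimulated genes went both ways, with 6 of 47 that rose and 2 that fell. Gbp2 had 74.9 ± 1.9 CPM with control siRNA and 934 ± 55.0 CPM with IRF2 siRNA (SD, n = 2 each), 12.5-fold higher. In the other direction Spn, which encodes the leukocyte sialoglycoprotein CD43, went from 54.2 ± 1.49 to 9.38 ± 0.294 CPM, 5.77-fold lower. Of 13495 genes tested, 241 passed an adjusted p under 0.05 in the edgeR quasi-likelihood test, of which 69 rose and 172 fell. At 0.01, 26 rose and 24 fell. Among the 241, 45 rose and 129 fell by at least 2-fold. The median log2 fold change was 1.20 for genes that rose and −1.21 for genes that fell, against −0.0015 for all genes tested. The count depended on the control libraries, which differed more from each other than the IRF2 siRNA libraries did. It was 1424 (391 rose, 1033 fell) without control replicate 1 and 1770 (710 rose, 1060 fell) without control replicate 2, and each of these contained all 241 genes. It was 238 and 237 without IRF2 siRNA replicates 1 and 2, of which 180 and 176 were among the 241.

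**Figure D2:**
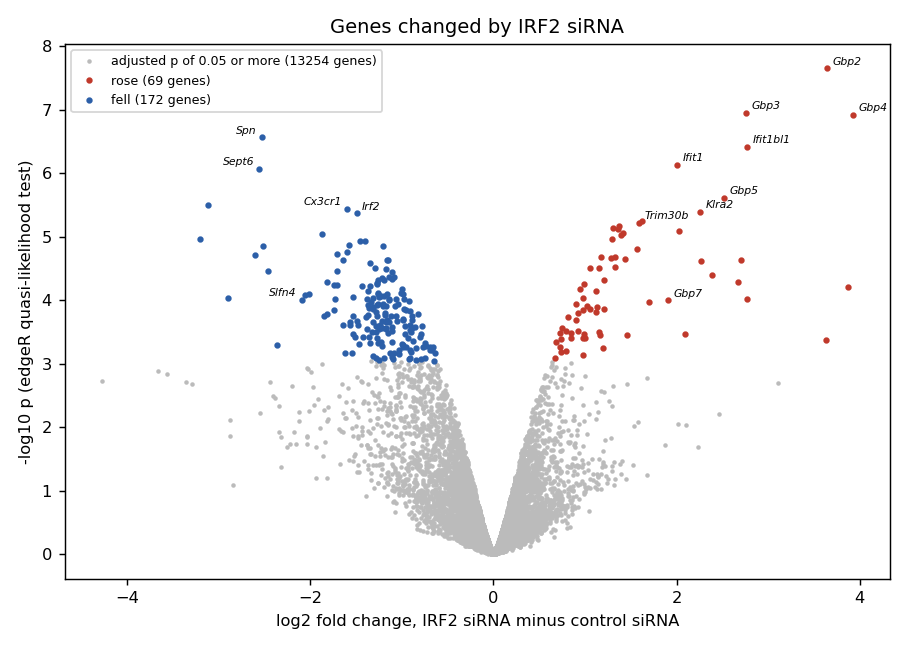
Log2 fold change of IRF2 siRNA minus control siRNA against −log10 of the unadjusted p of the edgeR quasi-likelihood test, 1 point per gene for 13495 genes. Red points are the 69 genes that rose and blue points the 172 that fell at an adjusted p under 0.05. Gbp2, Gbp3 and Gbp4 stand at the upper right, and Spn and Sept6 at the upper left.

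The 12 largest rises at a mean log2 CPM of at least 3 were in Gbp4, Gbp2, Ifit1bl1, Gbp3, Gbp5, Klra2, AW112010, Ifit1, Gbp7, Saa3, Tmem140 and Trim30b, with log2 fold changes from 3.92 down to 1.58. Klra2, a C-type lectin-like receptor of the Ly49 family, had a log2 fold change of 2.26 with a standard error of 0.17. Saa3, an acute-phase serum amyloid A gene expressed in macrophages, had one of 1.70 with a standard error of 0.21. The 12 largest falls were in Sept6, Spn, Slfn4, Ifi208, Ifi205, Treml2, Cx3cr1, Nxpe4, Ccnb2, Cenpf, Ccna2 and Tmsb10, with log2 fold changes from −2.55 to −1.42. Sept6, a septin of the cytoskeleton, went from 21.1 ± 0.252 to 3.59 ± 0.270 CPM (SD, n = 2 each). Cx3cr1, the fractalkine receptor of monocytes and macrophages, went from 69.4 ± 1.05 to 22.9 ± 1.15 CPM (SD, n = 2 each). Treml2, a receptor of the TREM family, and Tmsb10, an actin-binding thymosin, had log2 fold changes of −1.60 and −1.42. The control replicates lay far apart for Tmsb10, at 105.7 ± 34.4 CPM against 39.4 ± 2.5 CPM with IRF2 siRNA (SD, n = 2 each). Adjusted p-values of the edgeR test for the 24 genes ran from 0.0003 for Gbp2 to 0.0277 for Tmsb10. Exons of Tmem140 overlap Cyren, those of Ccna2 overlap Exosc9 and those of Gbp4 overlap Gbp8 and Gbp9. Those of Gbp2, Gbp7, Sept6 and Cx3cr1 overlap Mir6381, Gm43802, Gm15008 and Gm33858, and strand use in counting was not stated, so the values of these 7 genes are uncertain. Called genes named further down with such overlaps include Hk3, Ms4a4c, Tgm2, Kif20a, Top2a, Dusp1, Ndrg1 and Jun. The same uncertainty holds for their values.

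Interferon-gamma-type genes, a list of guanylate-binding proteins (GBPs), immunity-related GTPases and their regulators, were the list with the largest median change among 24 biological lists. Of 21 members tested, 10 rose and none fell over all genes, and 15 rose and 2 fell when adjusted over the list alone. The median log2 fold change was 0.98. Gbp2 and Gbp4 had log2 fold changes of 3.64 and 3.92, Gbp3 of 2.76 and Gbp5 of 2.51, with edgeR adjusted p-values of 0.0003, 0.000534, 0.000534 and 0.00412. GBPs are interferon-induced GTPases that act on intracellular pathogens and their vacuoles. The remaining members that rose, named after their values were seen, were Gbp6, Gbp7, Gbp8, Gbp9, Tgtp2 and Cd274, the last encoding PD-L1. Among members that did not pass over all genes, Irf1 had a log2 fold change of −0.11, and Ciita and Iigp1, the pair below 0 when adjusted over the list alone, had −0.39 and −0.78. Gbp2 lies on chromosome 3 at 142620602 to 142638008 and Gbp4 on chromosome 5 at 105115767 to 105139586. GBP genes are close paralogs and multiply mapped reads were left uncounted, so the split of reads between members is uncertain. The camera test gave an adjusted p = 3.37e-61 with the preset correlation, and adjusted p = 0.316 with an estimated correlation. The list count that rose was 14 and 15 without control replicates 1 and 2, and 11 and 9 without IRF2 siRNA replicates 1 and 2. Fallen members numbered 1 in 3 of these cases and 0 without IRF2 siRNA replicate 1.

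**Figure D3:**
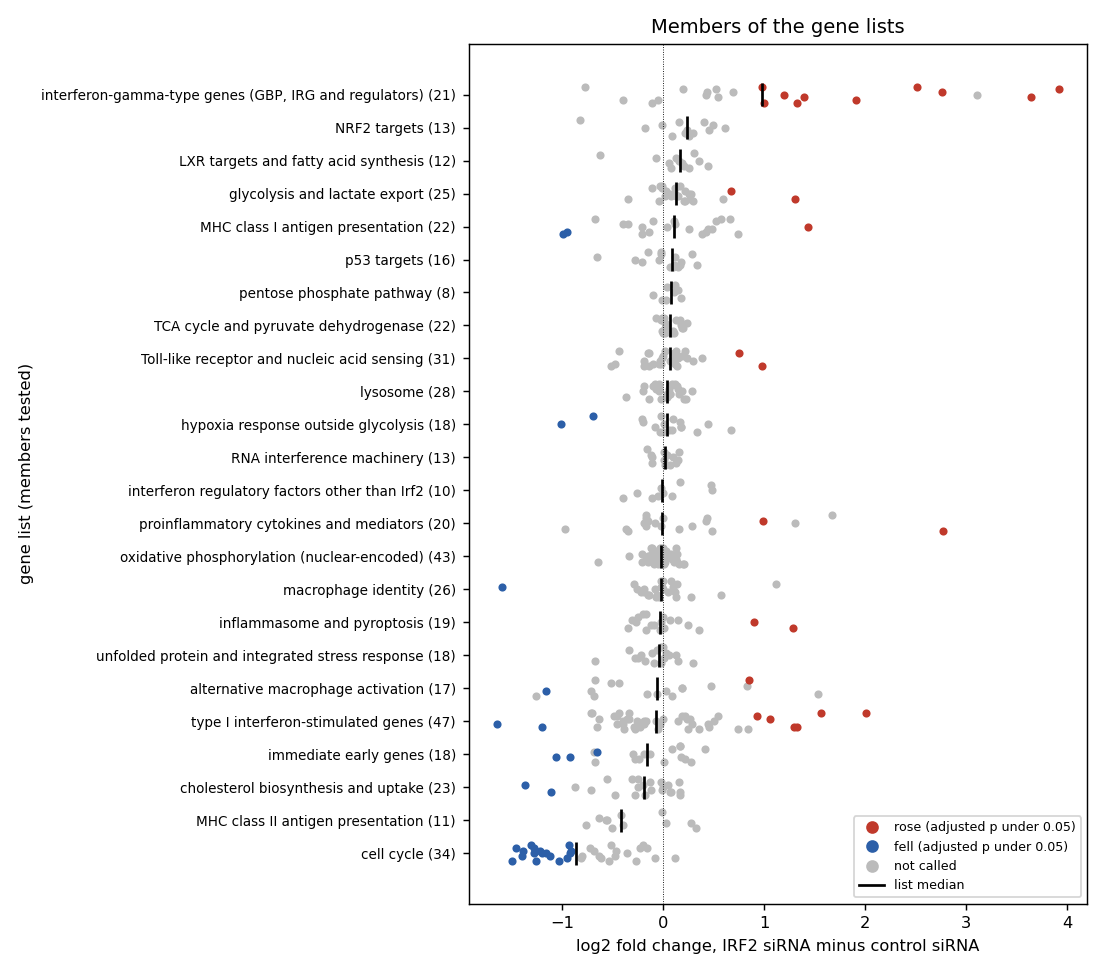
Log2 fold changes of IRF2 siRNA minus control siRNA for the tested members of the 24 biological gene lists, with the number tested in brackets. Each point is a gene, red where it rose and blue where it fell at an adjusted p under 0.05, and the black bar is the list's median. Interferon-gamma-type genes have the highest median, 0.98, and cell cycle genes the lowest, −0.86.

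Type I interferon-stimulated genes moved in both directions. Of 47 tested, 6 rose and 2 fell over all genes, and 12 rose and 14 fell when adjusted over the list alone. Ifit1 went from 120.9 ± 8.34 to 486.2 ± 1.03 CPM and Rsad2, which encodes the antiviral enzyme viperin, from 214.4 ± 33.8 to 635.6 ± 37.2 CPM (SD, n = 2 each). Ifit3 had a log2 fold change of 1.29 with an edgeR adjusted p = 0.00632. Ms4a4c had one of −1.20 with an edgeR adjusted p = 0.00668, and Ifi205, a member of the Ifi200 family of DNA sensors, one of −1.65 with an edgeR adjusted p = 0.0079. The other members that rose, named after their values were seen, were Cmpk2, Zbp1 and Isg15. The list's median was −0.07 and its mean 0.05, and the camera test pointed up without passing, with an adjusted p = 0.17, and adjusted p = 0.612 with an estimated correlation. It passed upward with the correction for length and GC content, with a limma camera adjusted p = 0.0274, and pointed down on ranks, with 0.782. Fry in limma, testing for changes in either direction, gave an adjusted p = 0.0029. The glycolysis, MHC class I and macrophage identity lists had the same value, so it does not set this list apart. The list had 14 and 13 members that rose and 16 and 13 that fell without control replicates 1 and 2. Ifit1, Ifit1bl1, Ifit3 and Ifit3b are related in sequence, so reads may be split between them.

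Among MHC class I presentation genes, 1 of 22 rose and 2 fell over all genes, and 8 rose and 3 fell when adjusted over the list alone. Psme2, a subunit of the proteasome activator PA28, had a log2 fold change of 1.43 with a standard error of 0.14 and an edgeR adjusted p = 0.0079. The non-classical class I genes H2-Q6 and H2-Q7 had log2 fold changes of −0.99 and −0.95, with edgeR adjusted p-values of 0.0198 and 0.0164. These genes are near-identical copies whose values are uncertain, and without IRF2 siRNA replicate 2 neither passed, with edgeR adjusted p-values of 0.0772 and 0.061. The list did not pass limma's camera test, with an adjusted p = 0.13, but passed upward without control replicate 1, at 0.0028, without IRF2 siRNA replicate 2, at 0.0182, and with a correction for length and GC content, at 0.0179. It had adjusted p = 0.913 with an estimated correlation in limma's camera. Its members that rose numbered 9 and 7, and those that fell 4 and 6, without control replicates 1 and 2; 1 rose and none fell without IRF2 siRNA replicate 2. MHC class II genes had a median log2 fold change of −0.42 over 11 members, with none past the threshold over all genes or adjusted over the list alone. H2-Eb1 and H2-Aa had −0.76 and −0.55, with edgeR adjusted p-values of 0.19 for both. The list passed the camera test with an adjusted p = 0.024, and had adjusted p = 0.883 with an estimated correlation. Its median differed by 0.46 between the control libraries, higher in replicate 1, and without that library the camera adjusted p was 0.556. With IRF2 siRNA replicate 2 left out it was 0.0571. Class II members that fell numbered 1 and 5 without control replicates 1 and 2. The mitochondrially encoded mRNAs had a median log2 fold change of −0.42 as well, and were also higher in control replicate 1.

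Innate sensing genes included 4 that rose. Casp1 and Casp4, the caspases of the canonical and non-canonical inflammasome, had log2 fold changes of 1.28 and 0.90 with edgeR adjusted p-values of 0.0079 and 0.02. They were the 2 of 19 members of the inflammasome and pyroptosis list that rose, with none falling, over all genes and adjusted over the list alone. The list's median was −0.03 while its mean was 0.06, and limma's camera test did not pass, with an adjusted p = 0.253. Without control replicates 1 and 2, 3 and 2 of its members rose and 2 and 1 fell, and without IRF2 siRNA replicate 1, 1 rose. Casp4 did not pass without IRF2 siRNA replicate 1, with an edgeR adjusted p = 0.0586. In the list of Toll-like receptors and nucleic acid sensors, 2 of 31 rose and none fell by both counts. These were Tlr4, the receptor for lipopolysaccharide, with a log2 fold change of 0.98 and an edgeR adjusted p = 0.0278, and Tlr2, with 0.75 and 0.0232. Tlr2 did not pass without IRF2 siRNA replicates 1 or 2, with edgeR adjusted p-values of 0.105 and 0.232. The camera adjusted p of this list was 0.229, and it passed upward without control replicate 2, with 0.0146, but had adjusted p = 0.913 with an estimated correlation over all 4 libraries. Without control replicates 1 and 2, 3 and 5 of its members rose and 5 and 1 fell.

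Proinflammatory cytokines and mediators had 20 of 31 members expressed enough to test. Over all genes 2 rose and none fell, and 5 rose and 2 fell when adjusted over the list alone. Ccl5, a chemokine for T cells and monocytes, went from 45.1 ± 1.24 to 89.2 ± 1.65 CPM (SD, n = 2 each), with an edgeR adjusted p = 0.012. Acod1, which makes itaconate, went from 2.04 ± 0.0651 to 14.0 ± 6.27 CPM (SD, n = 2 each), with an edgeR adjusted p = 0.0141. The list's median was −0.0078, below 0 with TMM and above 0 when scaled by library size alone, and its mean was 0.29. The camera test pointed up with an adjusted p = 0.0205, and adjusted p = 0.759 with an estimated correlation. The limma test did not pass without control replicate 2, with an adjusted p = 0.142, on ranks, with 0.681, or with the correction for length and GC content, with 0.0684. Members that rose numbered 6 and 5 without control replicates 1 and 2 and 3 without IRF2 siRNA replicate 1, and those that fell numbered 1 and 3 without control replicates 1 and 2.

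Cell cycle genes were lower with IRF2 siRNA. Of 34 tested, 17 fell and none rose over all genes, and 26 fell and none rose when adjusted over the list alone, with a median log2 fold change of −0.86. Ccna2, the cyclin of S phase and mitotic entry, went from 36.8 ± 2.44 to 13.4 ± 0.256 CPM, and Top2a, the topoisomerase of dividing cells, from 93.9 ± 11.3 to 41.0 ± 1.59 CPM (SD, n = 2 each). The mitotic kinesins Kif20a and Kif11 had log2 fold changes of −1.21 and −1.16, with edgeR adjusted p-values of 0.0111 and 0.0139. Ccnb2 and Cenpf, which act in mitosis, had −1.49 and −1.48. The camera test gave an adjusted p = 2.21e-43 with the preset correlation, adjusted p = 0.219 with an estimated correlation, and fry's test of the set moving 1 way gave an adjusted p = 0.0254. Between 13 and 25 members fell when a library was left out, with the highest count, 25, without either control replicate. Replication-dependent histones had a median of −0.19 over 5 members and none passed; Hist2h4 and Hist1h4i had log2 fold changes of −0.52 and −0.43, and 2 histone genes fell without control replicate 2.

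Among glycolytic genes, Hk3 and Pfkfb3 rose. Of 25 members of the glycolysis and lactate export list, 2 rose and none fell over all genes, and 3 rose and none fell when adjusted over the list alone, the additional gene being Aldoc at 0.60. The median log2 fold change was 0.13, and 19 of 25 members were above 0. Hk3, the hexokinase of myeloid cells that phosphorylates glucose, went from 150.1 ± 0.256 to 371.0 ± 0.418 CPM (SD, n = 2 each), with a log2 fold change of 1.31 and an edgeR adjusted p = 0.0059. Its exons overlap Unc5a. Pfkfb3, which makes the activator of phosphofructokinase, had a log2 fold change of 0.68 with a standard error of 0.12 and an edgeR adjusted p = 0.0463. It did not pass without IRF2 siRNA replicates 1 or 2, with edgeR adjusted p-values of 0.129 and 0.50. The camera test gave an adjusted p = 0.00101, adjusted p = 0.612 with an estimated correlation, and fry's test an adjusted p = 0.212. The members that rose numbered 3 and 4 without control replicates 1 and 2, and 1 without either IRF2 siRNA replicate.

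No member passed over all genes in the lists of the TCA cycle, with a median of 0.07 over 22 members, oxidative phosphorylation, with −0.02 over 43, and the pentose phosphate pathway, with 0.07 over 8, and none passed when adjusted over the list alone. The members with the smallest p were Mdh2 at 0.23 and Sdhb at 0.19 for the TCA cycle, Ndufa1 at −0.65 and Cyc1 at 0.20 for oxidative phosphorylation, and H6pd at 0.18 and Rpe at 0.15 for the pentose phosphate pathway. Camera adjusted p-values were 0.158, 0.899 and 0.53. The TCA cycle list passed upward without control replicate 1, with a limma camera adjusted p = 0.00868, on ranks, with 0.0272, and with the correction for length and GC content, with 0.0407. It had adjusted p = 0.913 with an estimated correlation in limma's camera. The oxidative phosphorylation median was above 0 when scaled by library size alone. Its direction also followed the control library used, with limma's camera pointing up without control replicate 1 at an adjusted p = 0.000957 and down without control replicate 2 at an adjusted p = 0.0021, where 8 members fell. Over all 4 libraries the camera adjusted p = 0.983 with an estimated correlation, which was 0.931 between its genes against the preset 0.01. Without control replicate 1, 1 member rose. Hypoxia-response genes outside glycolysis included 2 of 18 that fell, by both counts. These were Vegfa, an angiogenic growth factor, with a log2 fold change of −1.01 and an edgeR adjusted p = 0.0139, and Ndrg1, with −0.69 and an edgeR adjusted p = 0.0377. Vegfa did not pass without IRF2 siRNA replicate 1, with an edgeR adjusted p = 0.0555, and Ndrg1 without IRF2 siRNA replicates 1 or 2, with 0.309 and 0.39. In addition 1 hypoxia gene rose without control replicate 2. The hypoxia list had no fallen member without IRF2 siRNA replicate 1 and 1 without replicate 2, and its camera adjusted p was 0.899. Its median was 0.03 while its mean was −0.0012.

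Genes of cholesterol synthesis and uptake, 23 tested, had a median log2 fold change of −0.18. The camera test gave an adjusted p = 0.00123, and adjusted p = 0.434 with an estimated correlation. Immediate early genes, transcribed rapidly after stimulation, had 3 of 18 members that fell over all genes and 5 when adjusted over the list alone, with a median of −0.16. Nr4a1 had a log2 fold change of −1.06, Dusp1 of −0.92 and Jun of −0.65, with edgeR adjusted p-values of 0.0141, 0.0144 and 0.0497. Without IRF2 siRNA replicates 1 or 2, Nr4a1 alone of these 3 passed, and without control replicates 1 and 2 the list had 4 and 6 members that fell and 1 that rose in each. Camera gave this list an adjusted p = 0.00561, and adjusted p = 0.434 with an estimated correlation; it was 0.063 without IRF2 siRNA replicate 2 and 0.355 on ranks. NRF2 target genes, of the oxidative stress response, had a median of 0.24 over 13 members. None passed over all genes, and 3 rose when adjusted over the list alone. Without control replicates 1 and 2, 6 and 2 rose. Gsr and Hmox1 had log2 fold changes of 0.61 and 0.50 with edgeR adjusted p-values of 0.0745 and 0.155. This list's camera adjusted p was 0.00725, with adjusted p = 0.786 with an estimated correlation, and it did not pass without control replicate 2, with 0.122, or IRF2 siRNA replicate 1, with 0.0558.

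Macrophage identity genes had a median log2 fold change of −0.02 over 26 members, above 0 when scaled by library size alone. Cx3cr1 was the only member that fell over all genes and none rose, while 1 rose and 1 fell when adjusted over the list alone. Without control replicates 1 and 2, 3 and 2 of them rose and 2 and 6 fell. Alternative activation genes had 1 of 17 that rose and 1 that fell over all genes, and 4 and 3 when adjusted over the list alone. Clec7a, the beta-glucan receptor dectin-1, had a log2 fold change of 0.85 and Tgm2, a transglutaminase, −1.16, with edgeR adjusted p-values of 0.0253 and 0.0079. Clec7a did not pass without IRF2 siRNA replicates 1 or 2, with edgeR adjusted p-values of 0.0948 and 0.0576. Without control replicates 1 and 2, 3 members of this list rose in each case and 2 and 4 fell. Camera adjusted p-values were 0.757 for both lists. No member passed over all genes among LXR targets and fatty acid synthesis genes, the unfolded protein and integrated stress response, lysosomal genes, p53 targets and the RNA interference machinery, with list medians of 0.17, −0.04, 0.04, 0.08 and 0.02. When adjusted over the list alone, 1 fell in the stress response list and 1 among p53 targets, and none in the other 3. The members with the smallest p in these 5 lists were Abcg1 at 0.44 and Elovl6 at −0.62, Atf3 at −0.67 and Dnajb9 at −0.34, Gaa at 0.28 and Atp6v0d2 at −0.36, Pmaip1 at −0.66 and Btg2 at −0.28, and Drosha at −0.16 and Dicer1 at 0.16. Their camera adjusted p-values were 0.0675, 0.463, 0.53, 0.83 and 0.757. Without control replicate 2 the LXR list passed upward, with a limma camera adjusted p = 0.03, the stress response list downward, with 0.0342, and the RNA interference list upward, with 0.0104. Over all 4 libraries these 3 had limma camera adjusted p-values of 0.612, 0.913 and 0.913 with an estimated correlation. The LXR list also passed upward on ranks, with 0.0148, with no filter, with 0.0198, and with the correction for length and GC content, with 0.0261. Leaving out control replicate 1 gave 1 LXR gene that rose and 1 that fell, 1 stress response gene that fell, 1 p53 target that rose and 1 that fell, and 1 RNA interference gene that fell. Leaving out control replicate 2 gave 4 LXR genes that rose and 1 that fell, 5 stress response genes and 1 lysosomal gene that fell, 1 p53 target that rose and 1 that fell, and 4 RNA interference genes that rose.

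Neutrophil markers had a median log2 fold change of 0.27 over 7 tested, dendritic cell markers −0.30 over 8, B and plasma cell markers −0.29 over 4, megakaryocyte markers −0.19 over 6, fibroblast markers 0.16 over 11, endothelial markers −0.28 over 4 and osteoclast markers −0.15 over 8. Camera did not call any of these lists, with adjusted p-values from 0.216 to 0.994. The T and NK cell, erythroid, and mast cell, basophil and eosinophil lists had 2 tested members each and were not put to the set test. Over all genes the called members were Ccr3, a receptor of eosinophils, at −0.97 with an edgeR adjusted p = 0.0253, and Mmp9, a secreted protease also made by macrophages, at 0.98 with an edgeR adjusted p = 0.0253. Ccr3 did not pass without IRF2 siRNA replicate 1, with an edgeR adjusted p = 0.107. Leaving out a control library gave at most 1 gene that rose and 3 that fell in any of these lists. Adjusted over the list alone, those 2 passed and so did Il7r at −0.47 and Cd4 at −0.40, Itgax at −0.71 and Pf4 at −0.72. Other members with the smallest p were Lcn2 at 0.92, Mmp8 at −0.43, Dpp4 at −1.53, Ighm at 0.34, Igkc at −0.59, Ppbp at −2.25, Acta2 at 0.76, Col1a1 at 0.34, Kdr at −0.78, Pecam1 at 0.13, Tfrc at 0.39 and Epor at 0.25.

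Mitochondrially encoded mRNAs took 2.67% and 2.25% of counts in control replicates 1 and 2 and 2.10% in each IRF2 siRNA library. Their median log2 fold change was −0.42 over 10 tested, with mt-Nd5 at −0.44 and mt-Cytb at −0.50 and none past the threshold over all genes or adjusted over the list alone. The list passed the camera test with an adjusted p = 0.0168, and had adjusted p = 0.852 with an estimated correlation. It did not pass limma's camera without control replicate 1, with an adjusted p = 0.426, where 1 gene fell, or with the correction for length and GC content, with 0.0627, and without control replicate 2 it held 6 genes that fell. Cytosolic ribosomal protein genes had a median of −0.12 over 46 tested with a limma camera adjusted p = 0.175, none passing over all genes or adjusted over the list alone. The list passed downward without control replicate 2, with a limma camera adjusted p = 1.35e-12, without IRF2 siRNA replicate 1, with 9.57e-05, and on ranks, with 0.00311. These rest on the preset correlation of 0.01, while the estimated correlation was 0.967, with a camera adjusted p = 0.852 over all 4 libraries. Rps29 had a log2 fold change of −0.60 and Rpl5 of −0.45. Without control replicate 2, 22 of them fell, and without control replicate 1, 3 rose and 1 fell.

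Camera with its preset correlation called 8 of the 24 biological lists and 1 of the 10 technical lists put to it. None of these calls held with an estimated correlation, a form of the test with few degrees of freedom here. The estimate was −0.0434 for the cholesterol list, −0.0147 for immediate early genes and 0.0433 for the cell cycle, against the preset 0.01. It was from 0.135 to 0.82 for the other called lists. For the cholesterol and immediate early lists, a correlation above the preset is therefore not why the call was lost. The fewer degrees of freedom of that form of the test are. For the cell cycle list they are the main reason, as its unadjusted camera p went from 1.84e-44 to 0.00913 at a correlation near the preset. For the other called lists the 2 reasons were not separated. Fry, which asks whether a set's genes move on balance 1 way and does not compare them with other genes, called 2 biological lists, cell cycle and inflammasome.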

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

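Among the tests below, the comparison with the type I interferon list and the relation of the control libraries to transcript length were chosen after the result was seen, and the correction for GC content and length was added after the data were seen.

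The share of reads that HTSeq called ambiguous between overlapping genes, outside the gene counts, was higher in both IRF2 siRNA libraries than in both controls, with a mean of 4.6% against 4.28%. Single libraries had 4.38% and 4.17% with control siRNA and 4.71% and 4.49% with IRF2 siRNA. These reads are assigned to no gene, so no gene was tested for them. Of the 241 called genes, 68 have exons that overlap another gene, 28.2% against 37.1% of all genes tested.

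The rise of the interferon-gamma-type list was weighed first. Introduced RNA can set off a type I interferon response. Were that response, moving its genes alike, the whole cause, the type I list would rise by about as much, and its median log2 fold change was −0.0692, with 6 members that rose and 2 that fell. That argues against a uniform response and leaves a partial one open. Scaling is argued against, since it moves all genes alike and the list's median lay at least 0.979 from that of all genes. The 3 scalings shift both medians together, so repeating the comparison under each adds nothing. After removing the trend on GC content and length the median was 1.03, which argues against that trend as the whole cause. The 4 pairings of an IRF2 siRNA with a control library gave medians from 0.79 to 1.15, and the control libraries differed by −0.05. Sharing of reads between paralogs in the GBP family was not tested and stays open for the split between members. Release from repression by IRF2 is the hypothesis the design offers, and a direct effect on these genes cannot be separated here from an indirect one or from an effect of these siRNAs on other transcripts.

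The fall of the cell cycle list was weighed second. The 4 pairings of an IRF2 siRNA with a control library gave medians from −0.933 to −0.761, and the control libraries differed by 0.07. The difference between these control libraries was therefore smaller than the fall. The labels do not say whether replicates came from separate cultures. The pairings therefore cannot bound the spread between cultures, which stays open as a cause. After removing the trend on GC content and length the median was −0.82, which argues against that trend as the whole cause. A smaller share of dividing progenitors with IRF2 siRNA cannot be told apart from less division of the macrophages. Of 20 progenitor markers 6 were tested, with a median of −0.0513 and a bootstrap standard error of 0.324, so a fall of −0.432, 0.5 times the cell cycle median, lies within reach. Levels of these markers were from 0.382 CPM for Cd27 and 0.465 for Cd34 to 59.7 for Ifitm1 and 669 for Cd93, the last also expressed by macrophages. Log2 fold changes were −1.81 for Cd34, −0.567 for Sox4, −0.115 for Meis1, 0.0123 for Cd27, 0.0163 for Ifitm1 and 0.145 for Cd93. Lower proliferation with less IRF2 therefore remains a hypothesis.

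The difference between the control libraries was weighed last. Across 13458 genes, the log2 difference of control replicate 1 minus 2 had a Spearman rho of −0.546 with transcript length and 0.23 with GC content. The tenth of genes with the shortest transcripts had a median difference of 0.35, and the longest −0.44. Lnpep and Vps13c, named after their values were seen, were lower in replicate 1 by −1.78 and −1.5, and Uqcrb and Rplp2 higher by 0.78 and 0.715. The IRF2 siRNA libraries showed the same direction, with a rho of −0.402, and the contrast between groups one of 0.0462. The trend on both features accounted for 21.5% of the variance of the difference between controls and 10.2% of that between the IRF2 siRNA libraries, so most of either is left unexplained by it. RNA integrity, fragmentation and a biological difference between the cultures cannot be told apart, as the labels give no such measure. The lists that moved with the control library left out, among them MHC class II, oxidative phosphorylation, ribosomal protein genes and mitochondrial mRNAs, are best read with this in mind.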

How the results depend on the processing

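The correction for length and GC content was chosen after the result was seen. Irf2 was lower under all 14 alternatives run for it, with log2 fold changes from −1.55 to −1.43 (the range when a library is left out as well) and edgeR, limma or DESeq2 adjusted p-values up to 0.0318. No named gene that was called changed sign in any alternative, while Dicer1, not called, did. Against 241 genes (69 rose, 172 fell), counts were 240 with DESeq2 size factors, 231 with library size alone, 247 with a CPM filter, 238 with legacy = TRUE and 227 with limma-voom. They were 72 (31 rose, 41 fell) with no filter and 690 (172, 518) with the likelihood ratio test. DESeq2 gave 427 (120, 307), and the length and GC correction 701 (260, 441). A threshold of 0.01 gave 50 (26, 24) and a minimum absolute log2 fold change of 1 gave 174 (45, 129), fewer by construction. DESeq2, limma-voom and the length and GC correction shared 240, 226 and 240 genes with the 241. With the replicate number as a block the count was 1521 (503, 1018). The MHC class I, LXR and ribosomal protein lists then passed limma's camera, with adjusted p-values of 0.0467, 0.0467 and 0.00999. The deviations of replicates correlated at 0.373 between groups, and at 0.278 with the trend on length and GC content removed. A fall by more than 0.5 times was set, after the data were seen, as the mark of that trend as the source. It was not reached, and whether the trend is part of the source cannot be told. The labels name no pairing. Leaving out 1 library gave 237 to 1770 genes, 62 to 710 that rose and 171 to 1060 that fell, the highest without control replicate 2, and 7 to 11 lists. Lists called numbered 0 with an estimated correlation and 2 with fry, against 8. The glycolysis list, at a camera adjusted p = 0.00101, had 0.612 with an estimated correlation and 0.212 with fry, and from 0.000383 to 0.0443 with a library left out. The type I list, at 0.17, had 0.0274 with the length and GC correction. For oxidative phosphorylation, camera reversed without control replicate 2, at 0.0021, within 0.000957 to 0.179 over the libraries left out. Without IRF2 siRNA replicates 1 and 2, 10 and 8 named genes lost their call, and 25 with no filter. Where no reason is given, the cause was not tested. In the self-test 8 of 50 genes changed 1.5-fold were called, so changes of that size are mostly missed at this depth and replication.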

Other observations

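The test of neighbouring genes, its split by kind of neighbour and the calculation of the smallest seed effect that would pass were chosen after the result was seen, as were the genes and families named in this part, except those named in the report.

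In some families of related immune genes, more than 1 member was called in the same direction. The families were not tested as sets. In the PYHIN or Ifi200 family, which includes DNA sensors, 5 of 13 tested genes fell and none rose, with a median log2 fold change of −0.82. They were Ifi205 and Ifi208, with log2 fold changes of −1.65 and −1.71, and Ifi213, Ifi206 and Ifi211, with −1.20, −0.96 and −0.82. Among receptors of the Cd300 family, 3 of 11 fell and none rose, with a median of −0.58. These were Cd300ld, Cd300lf and Cd300e, with log2 fold changes of −1.18, −0.99 and −0.98. In the cluster of Trim5 and Trim30 genes, 3 of 10 rose and none fell, with a median of 0.34, while 3 of 4 H2-Q genes fell. Among 8 Schlafen genes the median was −0.70 and 1 fell, Slfn4. Members of these families are similar in sequence, so the split of reads between them is uncertain.

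Gsdmd, the gene for the pore-forming protein cleaved by caspases 1 and 4, had 148.9 ± 11.3 CPM with control siRNA and 148.6 ± 3.83 CPM with IRF2 siRNA (SD, n = 2 each), a log2 fold change of −0.0032 with a standard error of 0.12. Among genes in no list, Mir155hg, the host transcript of the microRNA miR-155, had a log2 fold change of 3.64, Hcar2 one of 2.27 and Bid, a mediator of apoptosis, one of 1.18. C1ra and C4b, of the complement system, had log2 fold changes of −3.12 and −2.06, Tnfsf13b, which encodes the B cell factor BAFF, −2.47, and Il1rl1, the receptor for interleukin 33, −1.82. All 7 were called by edgeR, and exons of Mir155hg overlap Mir155 and those of Bid overlap Bcl2l13. All except Bid changed by more than the last of the 12 largest changes in their direction. They were left out there because their mean log2 CPM was under 3, so their values rest on fewer reads. Of 31 genes with symbols that begin with Kif and a number, mostly kinesins, 8 fell and none rose, with a median of −0.16. Those that fell include Kif20a and Kif11 of the cell cycle list.

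Seed matches were tested as a reason why more genes fell than rose at an adjusted p under 0.05 (at 0.01, 26 rose and 24 fell), since an siRNA can lower transcripts whose 3' UTRs match its seed. The siRNA sequences were not used, so all 15556 heptamers found in the 3' UTRs of at least 100 of 10177 genes were scored. The cut-off in each pairing was the lowest score that any heptamer reached in any of 100 shuffles. The number whose carriers fell beyond it in both pairings was 0, and the number beyond the highest such score upward was also 0. To pass in both pairings, the carriers would have to differ from other genes by −0.18 on the log2 scale for a heptamer with 100 carriers and by −0.06 at the median of 918 carriers. An observed shift of −0.12 would pass for 83.1% of the heptamers. A true shift of that size could still be observed as smaller and be missed. No seed effect was detected, but the condition set beforehand, that no heptamer passes, was too weak to exclude one. Smaller effects, those of rarer seeds or of several seeds together stay open as a reason for the larger number that fell.

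The hypothesis that genes of tandem arrays change together was tested from gene order. Of 240 called genes with coordinates, 35 lay next to a gene called in the same direction. In 10000 random placements of the calls the median was 4 and the highest 20, giving p = 1e-04, the smallest these permutations can give. Such runs include Gbp5, Gbp7 and Gbp3 on chromosome 3, Gbp8, Gbp9, Gbp4 and Gbp6 on chromosome 5, Casp1 and Casp4 on chromosome 9, and Rsad2 and Cmpk2 on chromosome 12. Of the 35, 17 lay next to a gene whose symbol shares its first 3 characters, against at most 6 in the placements. Next to another gene whose span overlaps theirs lay 4, against a median of 0 and at most 8, with a permutation p = 0.05. Next to neither kind lay 14, against a median of 4 and at most 18, with a permutation p = 0.004. Membership of an array therefore cannot account for all of the excess. For the 17, shared regulation of duplicated genes and reads shared between paralogs cannot be told apart, and reads shared between overlapping genes stay open where spans overlap.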
